A study of Caenorhabditis elegans with 2 samples.

How the data were processed

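Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed with an anti-GFP antibody on whole young adult Caenorhabditis elegans. The worms carried a tag with eGFP inserted by CRISPR at nfya-2, which encodes an A subunit of the CCAAT-binding factor NF-Y. Per the labels, worms were collected at 64 hours after synchronisation as starved L1 larvae, chromatin was sonicated to 200 to 800 bp, and the 2 libraries are biological replicates of 1 group. No second strain, stage or untagged sample was analysed here, so no comparison between groups was made.

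The authors deposited peak lists, not reads. For each replicate and for the series there was a list of ranked regions and a thresholded list drawn from it. The series had such a pair for the replicates against each other, whose thresholded list is called conservative in its deposited name, and another pair here called pooled. Per the text that accompanies the deposited files, the lists are on assembly ce11 and derive from filtered alignments and a control; the aligner, the peak caller and their versions are not given in the sources used here. What each ranked list compared was read from its values. In the 200 strongest regions of the list behind the conservative peaks, 100% of the first replicate signals and 99.5% of the second equalled a signal in a per-replicate list. The other series list had the same intervals for 246 of the 281 conservative peaks, with the same signal at all 246. It is called pooled here for those signals, and what its IDR compared was not established.

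The deposited signal of each peak is the peak caller's own value for the reads used, and it was used only to rank and describe peaks within a list. The signal of a conservative peak exceeded both replicate signals in 276 of 281 peaks, and the median ratio to their sum was 0.990, so the series lists carry values of pooled reads. In 3 pairs of overlapping conservative peaks, both members carry the same replicate signals, and the weaker members are the 3 peaks below both of their replicate signals. The ranked lists also give −log10 of the global irreproducible discovery rate (IDR), which the authors computed. All 281 conservative peaks had an IDR of at most 0.01, and 101 further regions at that level were absent from the conservative list. The accompanying text names 1 further input for the thresholded lists without saying what it holds. No read counts or depths were in the files used here, so the depth of each library is unknown.

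Chromosome lengths of the reference genome (WBcel235, the same sequence as ce11) covered the highest peak ends on all chromosomes. Genes came from Ensembl release 115, with 46890 genes of which 19973 are protein-coding. A summit was placed in a promoter when it lay from 1000 bp upstream to 200 bp downstream of a gene start. Remaining summits went to exon, intron or intergenic sequence in that order. The background was the 71065 regions of the same ranked list that overlapped no thresholded peak of any of the 4 lists, among them the 101 regions absent from the conservative list. Words were searched on both strands within 100 bp of the summit: the core CCAAT, and the extended consensus RRCCAATSR, where R is A or G and S is C or G. Shares were compared by two-sided Fisher's exact tests, with conditional odds ratios and 95% intervals. Shares carry 95% Wilson intervals, which cover counting error only. Distances from the summit were compared by one-sided permutation tests with 100000 resamples. Overlap of the replicate lists needed 1 shared bp and was set against 1000 random placements on the same chromosomes, one-sided.

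The 22 gene lists were fixed before the data were examined, and so were the tests and the rule for named genes. Coding lists were compared with the other protein-coding genes, and tRNA, snRNA and snoRNA genes with all other genes. Their p-values were adjusted by the Benjamini-Hochberg method over the 22 lists. Named are the 15 strongest conservative peaks with their genes, up to 4 members of each list with a promoter peak by signal, the 4 NF-Y genes with egl-5 and tbx-2 whatever their values, and the members of counts of 5 or fewer. Lists of germline, intestine, muscle, neuron and collagen genes stood for tissues of the whole animal and served only as gene lists. The histone list held 80 gene identifiers under 58 symbols. In the cell cycle list, 58 of 59 names were matched.

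The tests were tried on simulated data. Of 200 random draws of 281 background regions, 3.5% gave a p-value under 0.05 for the promoter share, 4.5% for CCAAT and 4% for the extended consensus. These low rates follow from the test, since the draws came from the background they were tested against. They do not show how the tests handle the different GC content of the peaks. In 50 such draws, 0.455% of the gene lists tested passed the threshold. With the extended consensus planted in 5% of the windows, 100% of 50 draws passed. Alternatives changed the peak list, the left-out replicate, the background, the promoter and word windows and the assignment of peaks to genes. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.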

Results

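The NFYA-2::eGFP ChIP-seq of young adult worms gave 281 conservative peaks, 92 peaks in replicate 1 and 90 in replicate 2. The pooled list held 435 peaks. The depth of the libraries is unknown, so list sizes were not compared between replicates. The conservative peaks covered 66523 bp, and 272 of them were 240 bp wide. Their signals, in the authors' own units, had a median of 71.1 and ranged from 2.38 to 2244. The labels do not state which downstream question the series was made for, and the comparisons here address where the tagged protein was recovered, near which genes and at which sequence.

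The strongest conservative peak lay between Y22D7AL.10 and hsp-60, which encodes the mitochondrial chaperonin, on chromosome III from 1618974 to 1619291 (WBcel235). Its signal was 2244, with replicate signals of 994.6 and 1256. The summit was 609 bp upstream of the hsp-60 start and 204 bp upstream of the Y22D7AL.10 start, and the consensus site GGCCAATGG began at 1619126. The next peak, on chromosome II from 5660977 to 5661211, had a signal of 547 and lay 92 bp upstream of mdt-26, a Mediator subunit gene, and 303 bp upstream of ift-43, an intraflagellar transport gene. It held the site AGCCAATCA. A separate peak in an intron of mdt-26, with its summit 999 bp upstream of ift-43, had a signal of 234 and no extended consensus.

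In an intron of the cytosolic chaperone gene hsp-90, 302 bp upstream of C47E8.4, a peak had a signal of 315 and the site AACCAATCA. The peak 55 bp upstream of hsp-3, which encodes an endoplasmic reticulum Hsp70, had a signal of 276, with replicate signals of 96.9 and 178. It lay on chromosome X from 6092104 to 6092208. The peak 270 bp upstream of crt-1, the calreticulin gene, had a signal of 257 and replicate signals of 97.3 and 167, and lay on chromosome V from 6100751 to 6100862 in the exon of a non-coding gene. Both held the site GGCCAATCG, with its centre within 10 bp of the summit. A peak in an intron of ced-7, which encodes a transporter needed for engulfment of dying cells, had a signal of 227 and the site AACCAATCA. A peak 434 bp upstream of C55A6.12 had a signal of 198.7 and the same consensus on the other strand, as TGATTGGTT.

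**Figure D1:**
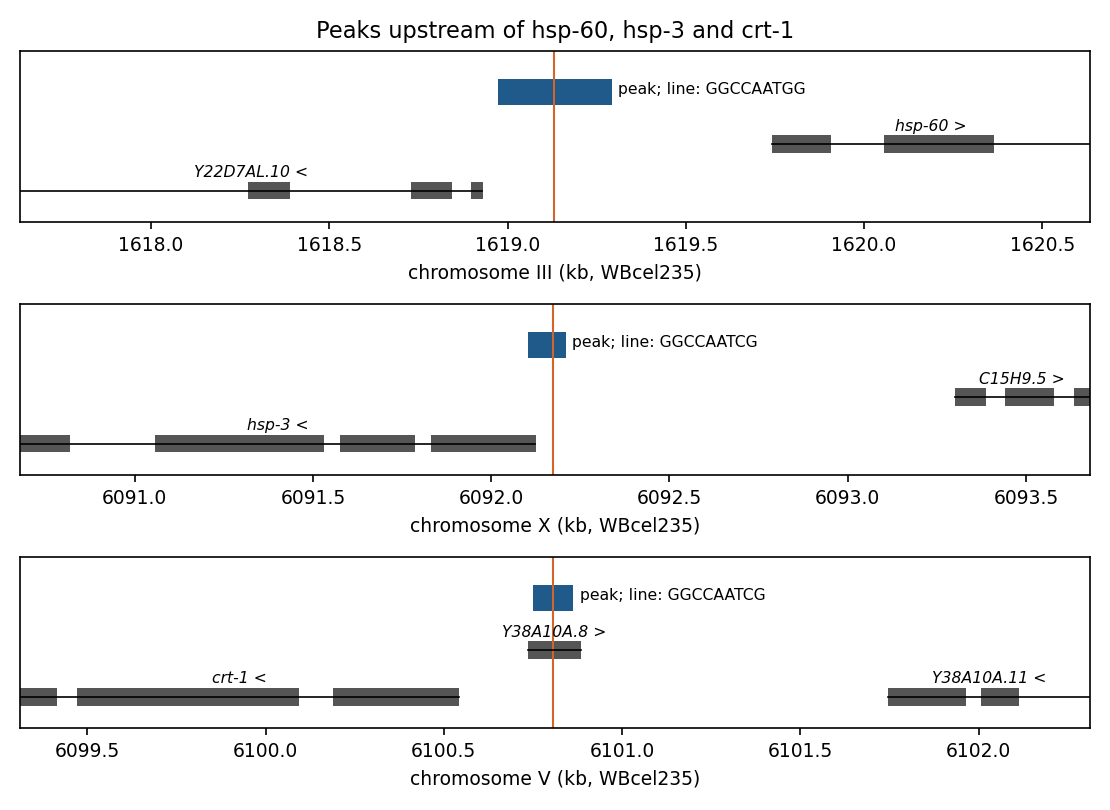
Maps of the peaks (blue bars) upstream of hsp-60, hsp-3 and crt-1, with exons as grey boxes and the direction of each gene as an arrowhead; the x axes give the position in kb. The orange line marks the extended consensus site, which lay inside each of the 3 peaks.

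The remaining 7 of the 15 strongest peaks lacked the extended consensus, as did the mdt-26 intron peak. They lay 265 bp upstream of rpl-3, a ribosomal protein gene (signal 217), 151 bp upstream of the non-coding gene WBGene00195021 (signal 170), 26 bp upstream of the snoRNA gene ZK994.7 inside pxn-1 (signal 163), and 638 bp upstream of rpa-2, which encodes a replication protein A subunit (signal 149). The others lay at the snoRNA genes C51F7.3 and C51F7.4 inside frm-7 (signal 146), between genes on chromosome IV, 734 bp from the piRNA gene 21ur-9399 (signal 144), and 231 bp upstream of sec-61.G, a translocon subunit gene that shares the promoter with F32D8.13 (signal 140).

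**Figure D2:**
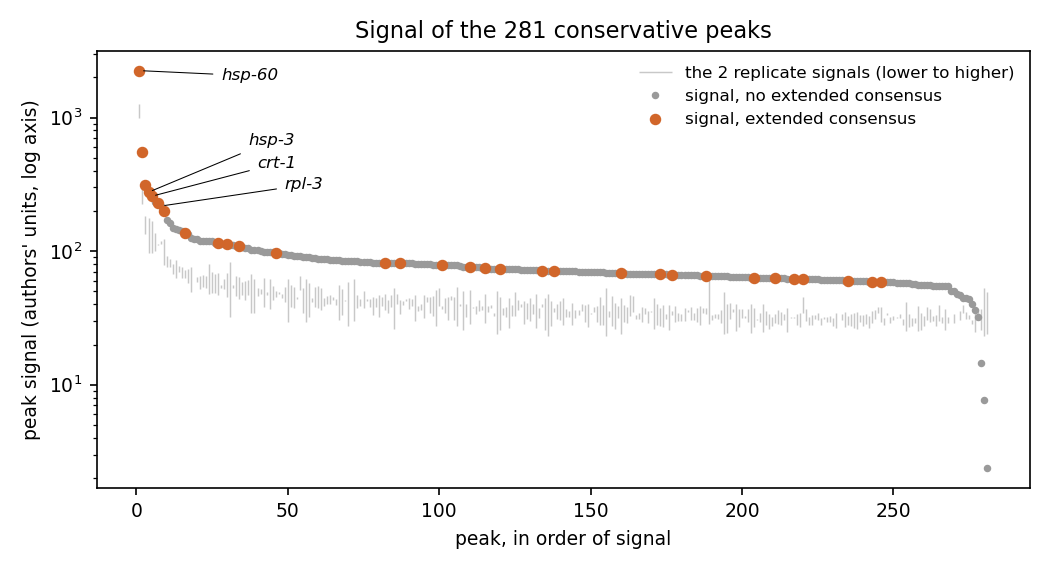
Signal of each of the 281 conservative peaks on a log axis, in order of signal, with grey lines from the lower to the higher of the 2 replicate signals. Orange points have the extended consensus within 100 bp of the summit, and 7 of the 10 strongest peaks are orange.

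The replicates shared far more peaks than uniform random placement gave. Of the 92 replicate 1 peaks, 46 overlapped a replicate 2 peak (50%, 95% Wilson interval 39.99 to 60.01%), and the hsp-60 peak was the strongest in both lists. Random placement gave a mean of 0.049 shared peaks and at most 2 (permutation p = 0.001, the smallest that 1000 placements can give). The placements did not keep the promoter location of the peaks. They therefore cannot tell shared binding from sites recovered in both replicates for other reasons. Of the conservative peaks, 45 overlapped both replicate lists and 175 overlapped neither. The 2 replicate signals at conservative peaks differed by a median of 1.24-fold, with no correction for an offset between the libraries (median log2 ratio 0.20). These peaks were selected by the IDR between the same replicates, so their agreement is not an independent measure. Across these 281 regions, which are not independent replicates, the rank correlation of the 2 signals was 0.29. Across all 71547 ranked regions it was 0.19. Without the 10 strongest conservative peaks, the correlation at the other 271 was 0.21.

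Conservative summits lay in promoters more often than background summits. The share was 59.4% (167 of 281, 95% interval 53.6 to 65.01%) against 34.2%, an odds ratio of 2.82 (2.21 to 3.61; Fisher's exact test, adjusted p = 4.8e-17 over 5 locations). Against the regions next below the threshold the odds ratio was lower, at 1.77 (Fisher's exact test, p = 9.7e-04). Promoters of protein-coding genes held 42.3% against 21.5%, and 145 coding genes had a promoter peak. Exons held 16.7% against 28.9% (odds ratio 0.495) and introns 9.61% against 23.0% (odds ratio 0.356), with adjusted p = 4.1e-06 and 1.4e-08 by Fisher's exact tests. Intergenic shares did not differ detectably, at 14.2% and 13.9% (Fisher's exact test, adjusted p = 0.86).

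**Figure D3:**
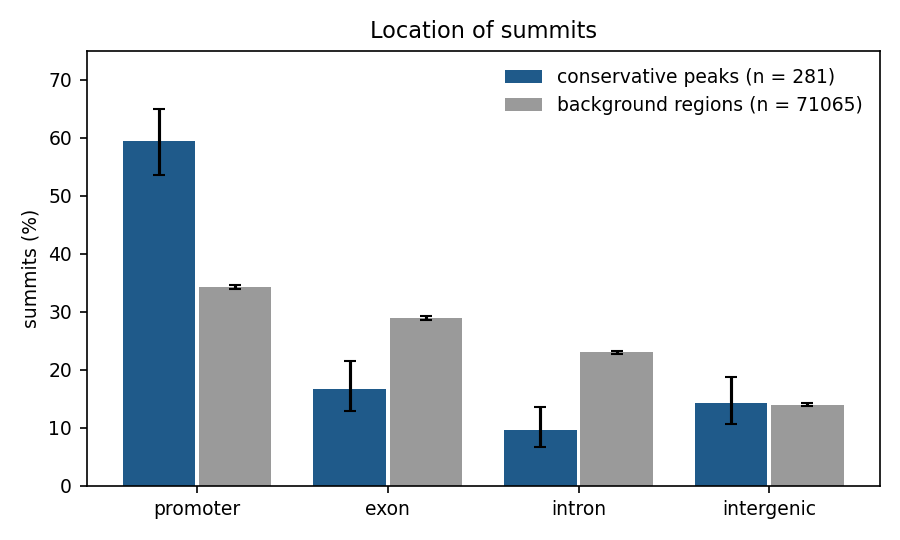
Share of summits in promoters, exons, introns and intergenic sequence for conservative peaks (blue) and background regions (grey), with 95% Wilson intervals. Promoters hold 59.4% of the peak summits and 34.2% of the background summits.

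Chromosome III held more conservative peaks than background regions (22.4% against 14.2%, odds ratio 1.74, adjusted p = 0.0015 over 7 Fisher's exact tests). Chromosome V held fewer (14.2% against 20.98%, odds ratio 0.625, Fisher's exact test, adjusted p = 0.012), and so did X (10.7% against 17.99%, odds ratio 0.545, 0.360 to 0.798, adjusted p = 0.0036). The X difference was not detectable against the regions next below the threshold (odds ratio 0.840, Fisher's exact test, p = 0.60) or in the replicate 1 list alone (odds ratio 0.573, p = 0.10). The central part of the chromosomes held 33.5% of peak summits and 34.3% of background summits (Fisher's exact test, adjusted p = 0.80).

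The extended CCAAT consensus, RRCCAATSR, was present at 31 of 281 conservative peaks (11.0%, 7.88 to 15.2%) and at 2.59% of background regions. The odds ratio was 4.65 (3.09 to 6.80; Fisher's exact test, p = 2.5e-11). The site was concentrated among the 10 strongest peaks, of which 7 had it (70%, 39.7 to 89.2%), against 24 of the other 271 (8.86%; Fisher's exact test, p = 9.8e-06). The next 15 peaks by signal did not continue this, with the site at 1 of them, the peak upstream of oxy-5. This division by signal was chosen after the data were seen. The other 271 peaks still exceeded the background, with an odds ratio of 3.65 (Fisher's exact test, p = 2.7e-07).

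The core CCAAT alone did not differ detectably between peaks and background, at 39.5% and 37.8% (odds ratio 1.08, 0.838 to 1.37; Fisher's exact test, p = 0.58), and took rank 197 among the strand-merged pentamers by odds ratio. The leading words were CGCGC (odds ratio 4.04), CACGC (3.89) and ACGCG (3.29), and 91 pentamers were more frequent and 66 less frequent at the peaks at an adjusted p under 0.05. Peak windows had a mean GC content of 43.4% ± 7.72 (SD) against 38.7% ± 7.10. Where CCAAT was present, it lay nearer to the summit, at a mean of 37.02 bp in 111 peaks against 44.1 bp in the background (permutation p = 0.0040). In the replicate 1 list alone this difference did not pass the threshold (permutation p = 0.053). Without the 10 strongest peaks the difference was -4.97 bp in place of -7.06 bp (permutation p = 0.036). The 111 peaks include the 31 with the extended consensus, so this is not a result for the core alone.

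**Figure D4:**
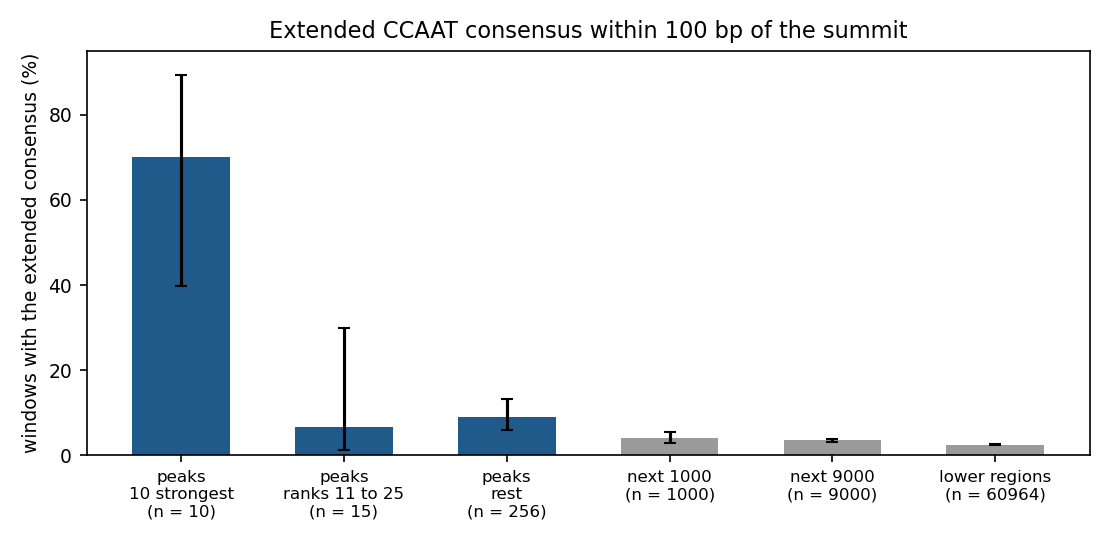
Share of windows with the extended consensus within 100 bp of the summit, with 95% Wilson intervals, for the 10 strongest conservative peaks, ranks 11 to 25, the other peaks (blue) and regions below the threshold in order of IDR (grey). The share is 70% in the 10 strongest peaks, 6.67% in ranks 11 to 25 and 2.44% in the lowest regions.

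Genes of the endoplasmic reticulum chaperone and unfolded protein response list had promoter peaks far more often than other coding genes. Of 26 members, 6 had one, against 0.697% of the others (odds ratio 42.7, 13.8 to 112.4; Fisher's exact test, adjusted p = 2.0e-07). This odds ratio depended on the list of peaks and on their assignment. It was 102.6 in the replicate 2 list alone, 84.3 in the replicate 1 list alone and 15.4 by the nearest gene start, where that of the ribosomal protein list was higher (19.5). The 6 genes included hsp-3, crt-1, sec-61.G and pdi-6, a protein disulfide isomerase gene with a signal of 113. The extended consensus was present at 4 of the 6, namely hsp-3, crt-1, pdi-6 and pdi-3. Some members were counted through peaks nearer to another coding gene. The pdi-3 summit lay nearer to ubql-1 (558 against 617 bp), and the sec-61.B summit nearer to trap-3 (255 against 515 bp). Of the heat shock and cytosolic chaperone list, 2 of 33 members had a promoter peak, hsp-60 and cct-8 (signal 106), and the list did not pass (Fisher's exact test, adjusted p = 0.087). It passed in each replicate list alone (Fisher's exact test, adjusted p = 0.018 in replicate 2 and 0.020 in replicate 1) and among the stronger conservative peaks (0.034).

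Ribosomal protein genes also had promoter peaks more often, 8 of 81 (odds ratio 15.8, 6.45 to 33.6; Fisher's exact test, adjusted p = 7.2e-07). The strongest lay at rpl-3, rpl-35 (signal 135), rpl-20 (118.7) and rpl-15 (96.2). None of the 8 had the extended consensus or CCAAT within 100 bp of the summit. One of the 8, rla-1, chosen here after its value was seen, was counted through the weakest conservative peak (signal 2.38). That peak overlaps a stronger one (signal 64.7) outside the promoter window and carries the same pair of replicate signals, so these are not its own measurements. Without the weaker peak of each of the 3 such pairs, an alternative chosen after seeing the data, the list still passed (odds ratio 13.6; Fisher's exact test, adjusted p = 1.1e-05).

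Small RNA genes formed the other large group. Promoter peaks were present at 24 of 346 snoRNA genes (21 distinct peaks, odds ratio 14.1, adjusted p = 1.4e-17), 20 of 612 tRNA genes (14 distinct peaks, odds ratio 6.27, adjusted p = 6.0e-09) and 6 of 129 snRNA genes (odds ratio 8.66, adjusted p = 4.6e-04), all by Fisher's exact test. The comparison genes here include 15363 piRNA genes, of which 0.137% had a promoter peak, against 0.726% of coding genes. These odds ratios are thus not on the same scale as those of the coding lists. The tests also count genes sharing a peak as independent, so their p-values may overstate the evidence. Random draws of as many background promoter regions as there were peaks in promoters gave expected counts of 2.88 snoRNA, 5.20 tRNA and 0.797 snRNA genes. The strongest at snoRNA genes were those at ZK994.7, C51F7.3, C51F7.4 and C06A1.9 (signal 113.5 at the last). The strongest at tRNA genes were those at WBGene00023221, which shares the ZK994.7 peak, WBGene00014474 (114), WBGene00014287 (84.8) and WBGene00014333 (77.6). Among snRNA genes these were F54D8.7 (81.5), WBGene00014543 (80.1) and the spliced leader genes sls-2.1 (78.1) and sls-2.2 (66.3). Some of these peaks were shared with coding genes, since the rpl-15 peak also lay upstream of snoRNA genes inside rpl-15, and the F54D8.7 peak also lay upstream of cox-6A. In the single-replicate lists, the tRNA list did not pass, with odds ratios of 2.50 in replicate 2 and 2.79 in replicate 1 (Fisher's exact test, adjusted p = 0.43 and 0.22). The snRNA list did not pass in replicate 2 (odds ratio 3.92; Fisher's exact test, adjusted p = 0.63).

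**Figure D5:**
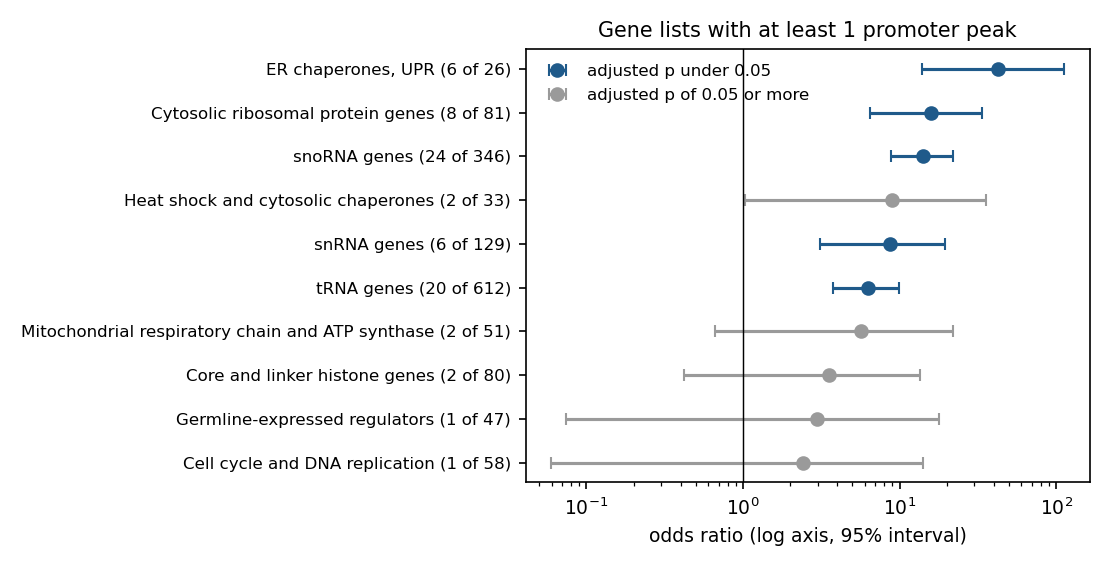
Odds ratio, on a log axis with 95% intervals, of a promoter peak in each list with at least 1 such gene; the counts stand beside the names and blue marks an adjusted p under 0.05. The endoplasmic reticulum list (ER, with the unfolded protein response as UPR) has an odds ratio of 42.7, with the promoter rule used here. Coding lists were compared with other coding genes and the small RNA lists with all other genes, so their odds ratios are not on the same scale.

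The other lists held few or no peaks. Respiratory chain genes had 2 of 51 (cox-5A, signal 85.9, and cox-6A, signal 81.5; adjusted p = 0.17), histone genes 2 of 80 (his-63, signal 81.8, and his-42, signal 61.8; adjusted p = 0.32), cell cycle genes 1 of 58 (rpa-2; adjusted p = 0.69) and germline regulators 1 of 47 (mex-1, signal 74.1; adjusted p = 0.64), all by Fisher's exact test. No promoter peak was present among 28 intestinal, 32 muscle, 38 neuronal, 174 collagen, 269 nuclear hormone receptor, 33 proteasome, 30 fatty acid, 30 insulin and stress, 31 major sperm protein or 6 Hox genes. With so few peaks, these zeros did not differ detectably from other genes (Fisher's exact test, adjusted p = 0.64 for nuclear hormone receptors and 1 for the rest).

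The NF-Y subunit genes themselves had no peak. None of the 4 lists held a peak within 2000 bp of nfya-2, nfya-1, nfyb-1 or nfyc-1, or of egl-5, a Hox gene, and tbx-2, a T-box gene, both on the list of genes reported as NF-Y regulated. The strongest below-threshold region at the tagged nfya-2 locus, on chromosome I from 11223390 to 11223629, had a signal of 30.8 and an IDR of 0.68, with 21.6% of all ranked regions above it. At nfya-1 the strongest signal was 34.4, at nfyb-1 40.3, at nfyc-1 43.2, at egl-5 34.9 and at tbx-2 36.0. In the same order, 13.4%, 5.75%, 3.85%, 12.5% and 10.6% of all ranked regions were above. The IDR of these regions ran from 0.27 to 0.69. The median ranked region had a signal of 23.0.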

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

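All tests in this part were chosen after the result was seen. The regions stand out because they carry signal in the ranked lists that the thresholded lists do not report.

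In the ranked list of the replicates, 101 regions reached the IDR of the conservative peaks but were absent from the conservative list, with a median signal of 118 and an intergenic place in 84 of them (83.2%). The strongest region of the whole ranked list was among the 101, on chromosome X from 15810999 to 15811180, with a signal of 2433, 6938 bp from the start of Y7A5A.7. Sequence present in several copies is a candidate explanation for their signal, since a median of 91.2% of the 31-base words in their windows (95% bootstrap interval 85.97 to 95.3%) occurred at 2 or more places in the genome, against a median of 0% in the 244 conservative peaks away from small RNA genes. The conservative list is not free of such sequence, since over 50% of the words were of this kind at 34 of these 244 peaks (13.9%), against 96 of the 101 regions (95.05%) and 3.9% of 2000 background windows (odds ratio of the 244 peaks against these 3.99, 2.52 to 6.21; Fisher's exact test, p = 5.5e-09). The extended consensus was present at 0 of the 101, which allows up to 2.97%, against 31 of 281 peaks (Fisher's exact test, p = 6.7e-05), which argues against binding through it. The bound and the test count the 101 regions as independent. Whether some are copies of one another was not examined, so both may overstate the evidence. Whether the authors removed these regions for their sequence was not tested, since the further input named for the thresholded lists was not used here.

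Of the 1000 regions next below the threshold, 40 (4%, 2.95 to 5.401%) held the extended consensus, and none of these regions is reported in a thresholded list. Against lower regions of the same GC content, 2.73% of which held it, the odds ratio was 1.48 (1.04 to 2.06; Fisher's exact test, p = 0.023). The 281 of them nearest the threshold showed little excess, since the odds ratio of the conservative peaks was 4.22 against these and 4.65 against the whole background. Weaker binding below the threshold may contribute to the small difference between the 1000 regions and the lower ones. However, the 9000 regions that follow, which are among the lower ones, held the site at 3.5%, inside the interval of the 1000. The difference is thus not particular to the regions nearest the threshold, and the comparison was not matched on promoter location.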

How the results depend on the processing

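The alternatives without the peaks near small RNA genes, without the 10 strongest peaks, without the 101 absent regions in the background, without the weaker peak of overlapping pairs, without windows mostly of multicopy words and at an IDR of at most 0.001 were chosen after seeing the data. The higher promoter share kept its direction and passed its test in 13 of 13 alternatives (odds ratio 1.77 to 4.12), as did the extended consensus in 15 of 15 (3.59 to 6.26), and the endoplasmic reticulum list (15.4 to 103), the ribosomal protein list (10.1 to 24.1) and the snoRNA list (5.20 to 16.01) in 10 of 10 each. The count of peaks was 435 in the pooled list, 63 at an IDR of at most 0.001, 278 without the weaker peak of overlapping pairs, 247 without windows mostly of multicopy words (over 50% of 31-base words at 2 or more places), and 90 and 92 without replicate 1 and without replicate 2; an IDR of at most 0.01 changed nothing, since the deposited list already had it. The rank correlation of the replicate signals was 0.29 at the conservative peaks and 0.30 in the 1000 regions of highest mean rank. For CCAAT the odds ratio fell below 1 with a window of 150 bp (0.988) and in promoters (0.924, with rank 298 among the pentamers), and ran from 0.995 to 1.14 with a replicate left out. Its distance from the summit differed by -15.3 to -7.36 bp with a replicate left out, and the test passed without replicate 1 but not without replicate 2. The difference was -4.38 bp in the pooled list and -4.97 bp without the 10 strongest peaks (permutation p = 0.024 and 0.036). In the stronger peaks it was -9.54 bp, and by the median distance -12 bp (permutation p = 0.0056 and 0.0059). The X odds ratio was 0.840 against the next regions and 0.428 to 0.573 with a replicate left out. The odds ratio of chromosome centres was 1.08 in the pooled list, 1.03 in the stronger peaks, 1.03 against random positions, 1.02 without windows mostly of multicopy words, and 0.787 to 1.02 with a replicate left out, never past its test. Without the peaks near small RNA genes, 3 gene lists passed in place of 5. The odds ratios of the tRNA and snRNA lists were then 0.397 and 0, by construction. The snoRNA list still passed (odds ratio 5.20; Fisher's exact test, adjusted p = 0.0043). However, its remaining peaks all had a coding gene start nearer to the summit, that of cdc-48.1, rpl-15, rps-23, rpl-7A or fbxl-2. That pass therefore cannot tell snoRNA genes from the coding genes that share these peaks. Using the nearest gene start, the heat shock list had an odds ratio of 0. By that rule neither of its peaks counted. Y22D7AL.10 started nearer to the summit than hsp-60 (204 against 609 bp), and Y55F3AR.2 nearer than cct-8 (180 against 441 bp). The respiratory chain list passed in the pooled list (odds ratio 6.52, Fisher's exact test, adjusted p = 0.048), while without replicate 2 its odds ratio was 0; with a replicate left out it ran from 0 to 7.95. For the other changes the cause was not tested. Fewer peaks in the single-replicate lists leave less power, and unknown depth limits what their zeros show. No paired analysis was possible because there is 1 group.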

Other observations

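The tests of GC content, of shuffled consensus words and of gene copies over all small RNA peaks were set before their results were seen. The tests of distance, of the consensus at small RNA genes, of copies by kind of small RNA, of peak width and of the stress element were chosen after.

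Peaks that differed in width also differed in sequence. While 272 conservative peaks were 240 bp wide, 8 were narrower, and 6 of these 8 had the extended consensus, against 25 of the other 273 (odds ratio 29.0, 4.86 to 308; Fisher's exact test, p = 2.7e-05). The narrow peaks with the site were those at mdt-26, C47E8.4, hsp-3, crt-1, ced-7 and C55A6.12. All 8 were among the 10 strongest, so width and signal were not separated.

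The higher frequency of the extended consensus at the peaks was weighed first. GC content alone is argued against, since the odds ratio was 4.02 (2.59 to 6.07) against background windows of the same GC content. Base composition is argued against too, since 0 of 500 versions of the consensus with shuffled positions reached its odds ratio, which was 4.72 when computed as for the shuffled words, from the counts with a small constant added to each and not as the conditional estimate used elsewhere; the highest of the shuffled words had 4.28. Binding at the site itself is consistent with its place, a mean of 32.0 bp from the summit against 44.5 bp in the background (permutation p = 0.0062). Much of this difference came from the 7 sites among the 10 strongest peaks, with a mean of 10.6 bp. At the 24 sites of the other peaks the mean was 38.2 bp and did not differ detectably from the background (permutation p = 0.14), so whether binding at the site holds for them cannot be told. It remains a hypothesis, found and tested on the same peaks, of which 31 of 281 have the site.

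The peaks at small RNA genes were weighed next. Of the conservative peaks, 37 (13.2%) lay within 300 bp of the start of a tRNA, snoRNA, snRNA or rRNA gene, against 0.992% of the background (odds ratio 15.1; Fisher's exact test, p = 4.0e-29). Binding through the extended consensus is at most weakly argued against. It was present at 0 of the 37, which allows up to 8.11%, against 31 of the other 244 (Fisher's exact test, p = 0.020). Of those 31, 7 were among the 10 strongest peaks. Over all 271 peaks other than the 10 strongest the share was 8.86%, near that bound, so the contrast leans on the strongest peaks. Over all 37, a median of 8.19% of the 31-base words occurred at 2 or more places. This met the bound of under 10% set beforehand for excluding reads shared between gene copies. Its bootstrap interval (0 to 26.9%), not part of that rule, crosses the bound, so such reads cannot be told apart from other causes. Nor can they for the 12 at tRNA genes, whose median of 27.5% lies between that bound and the 50% set for accepting them. For the 25 at other small RNA genes the median was 0%, and 17 windows held no such word, which argues against shared reads at those 17. The other windows held up to 48.0%, and snRNA genes were not separated from snoRNA genes, so for them it cannot be told. Unspecific recovery of highly transcribed genes stays open and untested, since no unrelated factor or untagged strain was analysed here. It could also apply to the ribosomal protein genes. The same limit holds for every other gene list, the endoplasmic reticulum list included, where the sec-61.G and sec-61.B peaks lacked the extended consensus.

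For the endoplasmic reticulum genes, the composite stress element (CCAAT, 9 bases, CCACG) was a further hypothesis. It was present at 0 of the 6 peaks of the list and at 0 of all 281 conservative peaks, against 0.0295% of the background, so that element as written does not account for the list.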
